A study of Homo sapiens with 12 samples.

How the data were processed

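Gene expression of U266 cells was measured on Illumina HumanHT-12 v4 BeadChips, with 12 arrays in 4 groups of 3 replicates: DMSO at 24 h, SAHA at 24 h, MO-OH-Nap at 24 h and MO-OH-Nap at 48 h. The deposited table of unnormalized values gives an intensity per probe and array, and per the file headers a detection p-value (p_value) beside each one. The second deposited table gives log2 values. The series design text names lumi for normalization, background correction and quality control, and limma for the tests, with versions not given in the sources used here. The deposited log2 values equal the quantile-normalized log2 intensities within 5.0e-09, so no background correction is visible in them. The names of the 47318 probes came from a table of the platform's probes: 30112 had 1 gene symbol, 8 had several and 17198 had none, giving 20045 distinct genes. No genome build is stated, and no coordinates are used.

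Intensities were background-corrected, put on the log2 scale and quantile-normalized with neqc (limma 3.58.1 in R 4.3.3, offset 16), which takes the background from the detection p-values. Probes with a detection p below 0.05 on at least 3 arrays were kept (21489). Each gene was represented by its probe with the highest mean log2 intensity, and probes without exactly 1 symbol were kept as unnamed features. This left 11689 named genes and 5823 unnamed probes, 17512 in all, and 3131 genes had more than 1 detected probe. A linear model with 1 mean per group was fitted to all 12 arrays with lmFit and eBayes (limma), with 8 residual and 10.9 total degrees of freedom. The tests are two-sided and adjusted by the Benjamini-Hochberg method over all 17512 features in each comparison. A call needs an adjusted p below 0.05 and at least a 1.5-fold change, the fold named in the design text, which does not say whether its p was adjusted. For a gene not detected on any array of 1 group the fold is given as a lower bound against the background level. Intervals of differences are 95% intervals from the same fit. The comparisons are SAHA, MO-OH-Nap at 24 h and MO-OH-Nap at 48 h against DMSO, MO-OH-Nap against SAHA at 24 h, and MO-OH-Nap at 48 h against 24 h.

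The genes named were chosen by a rule. Per comparison it takes the 6 largest rises and the 6 largest falls (5 and 5 between treatments) among called genes with 1 symbol whose arrays do not overlap between groups, up to 3 called members of each gene list by size, and the 11 measured genes of a fixed set (CDKN1A, DDIT3, ATF4, HSPA5, XBP1, TFRC, HMOX1, MYC, IRF4, CCND1 and MKI67). Of the genes that moved in opposite directions it takes the 5 with the largest difference. Genes given only as the called members of a list are named for their count. With a gene counted once in each comparison that names it, the rule gave 410 values, of which 384 were calls.

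The 28 gene lists were ATF4 and CHOP targets, ER chaperones with ER-associated degradation factors, cytosolic heat shock, metallothioneins with a zinc exporter, iron handling, hypoxia-inducible factor targets, glycolysis, mitosis, DNA replication, CDK inhibitors, p53 targets, antiapoptotic and proapoptotic BCL2 genes, histone genes, HDAC enzymes, histone demethylases, neuronal genes, plasma cell identity, B cell markers, MHC class II, T cell or myeloid markers, stromal or epithelial markers, cholesterol synthesis, NRF2 targets, NF-kB targets, interferon genes, ribosome biogenesis and autophagy. Some genes stand on more than 1 list, such as XBP1 and KDM3A. Each list was tested with camera (limma) at its preset correlation of 0.01, adjusted over the 28 lists in each comparison, and again with an estimated correlation and with fry, which asks whether the genes of a list move 1 way without comparing them with other genes. Members are counted as higher, lower or not past, over all genes tested and adjusted over the list alone. These choices, the comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. A further 7 lists, named where their results are given, were chosen after the values were seen. Their adjusted p is over those 7 lists in each comparison, not over the 28.

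Sharing of the 3 DMSO arrays by both compounds was examined in 100 simulations of unchanged groups. Alternatives covered the deposited log2 values, quantile normalization without background correction, an offset of 50, median scaling, no filter and a stricter one (detection p below 0.01), averaging or separating the probes of a gene, fitting only the groups compared, replicate number as a block, eBayes with trend and robust settings, array weights, other thresholds (among them 2-fold and treat), and leaving out each array in turn. Median scaling took the median over all 47318 probes of an array. Of these 38.0% to 41.6% were detected, so the median rests on probes mostly not detected. Replicate numbers do not pair the arrays: after group means were removed, 1 of 12 arrays correlated best with arrays of its own number.

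The procedure was tested on simulated data with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold on arrays drawn from the spread of these. A further set of 20 genes was raised 1.5-fold together. Of 2-fold changes 74.6% to 86.6% were called, of 4-fold changes 97.0% to 100%, and of 1.5-fold changes 25.4% to 43.3%, with 4 to 10 calls among 17292 unchanged genes per comparison. In the data 4401 to 7454 features passed the adjusted p, far more than were changed in the simulation. The adjustment depends on that share, so these rates need not hold for the comparisons here. Not analysed here were probes without a symbol as named items and the chips on which arrays lay, which the labels do not give.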

Results

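Total RNA of U266, an established human multiple myeloma cell line, was measured on 12 Illumina HumanHT-12 v4 arrays in 4 groups of 3. The groups were DMSO for 24 h (the solvent control), SAHA for 24 h, MO-OH-Nap for 24 h and MO-OH-Nap for 48 h. SAHA (vorinostat) is a histone deacetylase inhibitor. MO-OH-Nap is known here only by its name. The doses are not given in the sources used here, and no DMSO sample was taken at 48 h. Each array read 47318 probes, with a median signal of 116.1 to 141.8 intensity units and 17967 to 19692 probes detected (38.0% to 41.6%). The number of arrays limits the precision of every value. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so each p-value measures the spread between arrays, which may be technical. Log2 intensities correlated at 0.991 to 0.993 between arrays of 1 group and at 0.957 to 0.982 between arrays of different groups. Component 1 of the log2 intensities (40.2% of the variance) parted SAHA from MO-OH-Nap, and component 2 (29.4%) parted DMSO from the treated arrays. Fold changes below are log2 differences between group means ± SE with n = 3 arrays per group. A gene is called higher or lower at an adjusted p below 0.05 and a change of at least 1.5-fold, out of 17512 genes and unnamed probes tested. A gene whose value did not pass missed the adjusted p, the 1.5-fold change or both, so it need not be unchanged. With SAHA, for example, TFRC had adjusted p = 0.032 and missed the fold alone.

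**Figure D1:**
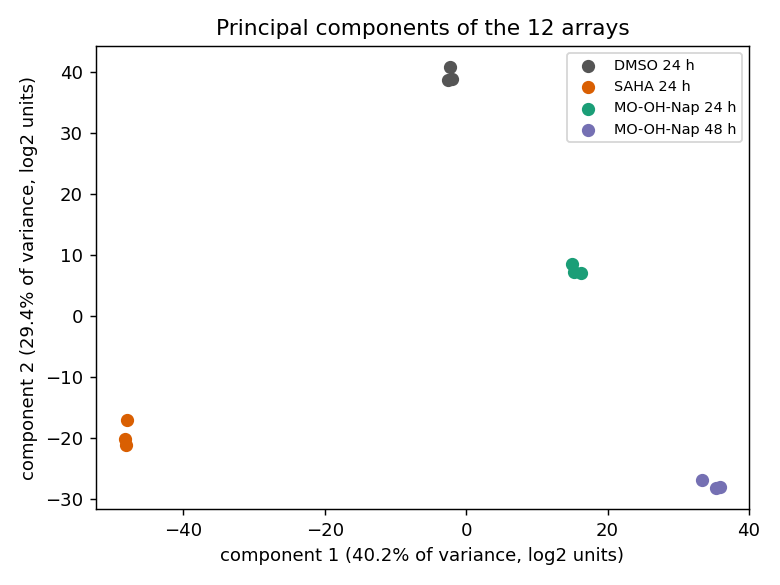
Principal components of the normalized log2 intensities of the 12 arrays, component 1 (40.2% of the variance) on the x axis and component 2 (29.4%) on the y axis, both in log2 units. Each point is 1 array, coloured by group, and the 3 arrays of each group lie together and apart from the other groups.

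The first question was what SAHA changed after 24 h. DNA replication genes fell nearly as a block: 20 of 22 measured members were lower than with DMSO and 0 were higher. CDC45 changed by −2.29 ± 0.08, the helicase subunit gene MCM5 by −2.16 ± 0.08 and the ribonucleotide reductase gene RRM2 by −1.89 ± 0.09. MHC class II genes, which serve antigen presentation, rose in 6 of 6 cases, with HLA-DMB at 3.42 ± 0.10, HLA-DRB1 at 2.19 ± 0.17 and HLA-DRA at 1.98 ± 0.08. CDKN1A, which encodes a cyclin-dependent kinase inhibitor, rose by 2.45 ± 0.07 (adjusted p = 3.8e-09), and the cyclin gene CCND1 changed by −1.31 ± 0.08 (adjusted p = 4.3e-07). Of the plasma cell identity genes, 11 of 17 fell and 1 rose. The immunoglobulin assembly factor MZB1 was at −1.92 ± 0.15, FCRL5 at −1.63 ± 0.12 and the transcription factor XBP1 at −0.81 ± 0.08. CD38, not detected with DMSO, was at least 2.58-fold higher with SAHA.

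Under SAHA the histone genes rose in 6 of 12 cases, with H2AC6 at 1.08 ± 0.10, H2BC21 at 1.06 ± 0.09 and the linker histone gene H1-2 at 1.01 ± 0.09. Neuronal genes rose in 6 of 10 cases, among them the tubulin gene TUBB3 (2.88 ± 0.18) and the neurofilament gene NEFL (1.81 ± 0.14). Metallothioneins, which bind metals, rose in 5 of 7 cases, with MT1X at 2.58 ± 0.09 and MT2A at 1.72 ± 0.16. Of the ATF4 and CHOP targets, which belong to the integrated stress response, 10 of 22 fell, such as PSAT1 (−1.51 ± 0.08), SLC7A11 (−1.50 ± 0.14) and STC2 (−1.44 ± 0.12), and 2 rose, ATF3 and DDIT3. DDIT3 stood at 0.70 ± 0.10 (adjusted p = 0.0002), and its call was lost without background correction and with median scaling. ATF4 itself was at −0.86 ± 0.07 (adjusted p = 2.1e-06) on its brightest probe, but its other detected probes ranged from −1.14 to 0.58 and the call was lost when probes were averaged. Ribosome biogenesis genes fell in 7 of 15 cases, with NOP56 at −0.98 ± 0.07 and NOLC1 at −0.91 ± 0.09. Of 18 ER chaperone and ER-associated degradation genes, CRELD2 and XBP1 fell and 16 did not pass. CRELD2 (−0.68 ± 0.08) lost its call without background correction. Among 18 hypoxia-inducible factor targets 6 rose, such as NDRG1 (1.66 ± 0.11) and P4HA2 (1.60 ± 0.09), and the glucose transporter gene SLC2A1 fell. Of 19 mitosis genes 1 was called, CCNA2 (−0.95 ± 0.07), and 2 were lower when adjusted over the list alone.

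The genes with the largest rises under SAHA were AKR1C3 (4.51 ± 0.14), an aldo-keto reductase, COXFA4L3 (4.28 ± 0.09), SERPINE2 (4.19 ± 0.13), HPCAL4 (4.02 ± 0.14), CDR2L (3.65 ± 0.17) and PTPRF (3.64 ± 0.11). With DMSO, SERPINE2, CDR2L and PTPRF were detected on 2 of 3 arrays and HPCAL4 on 1 of 3. The other detected probes of COXFA4L3 gave 0.83 to 2.21 and that of PTPRF gave 1.67. The largest falls were those of the potassium channel genes KCNK12 (−3.46 ± 0.09) and KCNN3 (−2.88 ± 0.19), LIME1 (−2.75 ± 0.10), LPXN (−2.60 ± 0.10) and the glycine transporter gene SLC6A9 (−2.52 ± 0.14), and ADTRP, not detected with SAHA, was at least 3.69-fold lower. The other detected probe of KCNN3 gave −0.08 and those of SLC6A9 gave −0.16 to −0.04. HMOX1 (heme oxygenase) was at 0.72 ± 0.12 (adjusted p = 0.00062), a call lost without background correction and with median scaling. Values that did not pass were −0.41 ± 0.07 for HSPA5, −0.20 ± 0.07 for TFRC, −0.20 ± 0.14 for MYC, −0.37 ± 0.08 for IRF4 and −0.63 ± 0.23 for MKI67. MKI67 passed in 6 other settings, among them without DMSO replicate 3 (−0.93) and without SAHA replicate 2 (−0.80), and HSPA5 and IRF4 passed with median scaling.

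In total SAHA changed 3687 genes and probes, 1929 higher and 1758 lower, of which 1319 changed at least 2-fold. By camera, 11 of the 28 lists passed. The calls for DNA replication (adjusted p = 1.3e-12, and adjusted p = 0.022 with an estimated correlation), MHC class II (1.9e-05, and adjusted p = 0.022 with an estimated correlation) and ribosome biogenesis (0.00063, and adjusted p = 0.029 with an estimated correlation) held with both. Those for plasma cell identity (5.8e-05) and for metallothioneins (0.0024) did not, with adjusted p = 0.062 and adjusted p = 0.078 with an estimated correlation. Nor did ATF4 targets (0.008), ER chaperones (0.015) and mitosis (0.025), each with adjusted p = 0.078 with an estimated correlation, or histone genes (0.015), with adjusted p = 0.11 with an estimated correlation. Neuronal genes (0.022) came to adjusted p = 0.28 with an estimated correlation, and hypoxia targets (0.044) to adjusted p = 0.51 with an estimated correlation. The other 17 lists had adjusted p from 0.11 to 0.87. Median, mean and test differed in sign for the histone demethylases and the B cell markers, neither past the test. Apart from mitosis, every list gave the same counts adjusted over the list alone. Without background correction 1739 genes and probes were called. Each array was also scaled to the median of all its probes, most of them not detected. The share of calls that were higher then moved from 52.3% to 35.2%, and the median of all genes shifted to −0.10. In that setting 6 ER chaperones, 10 mitosis genes and 11 ribosome biogenesis genes were lower. The hypoxia list was lost (camera adjusted p = 0.12).

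**Figure D2:**
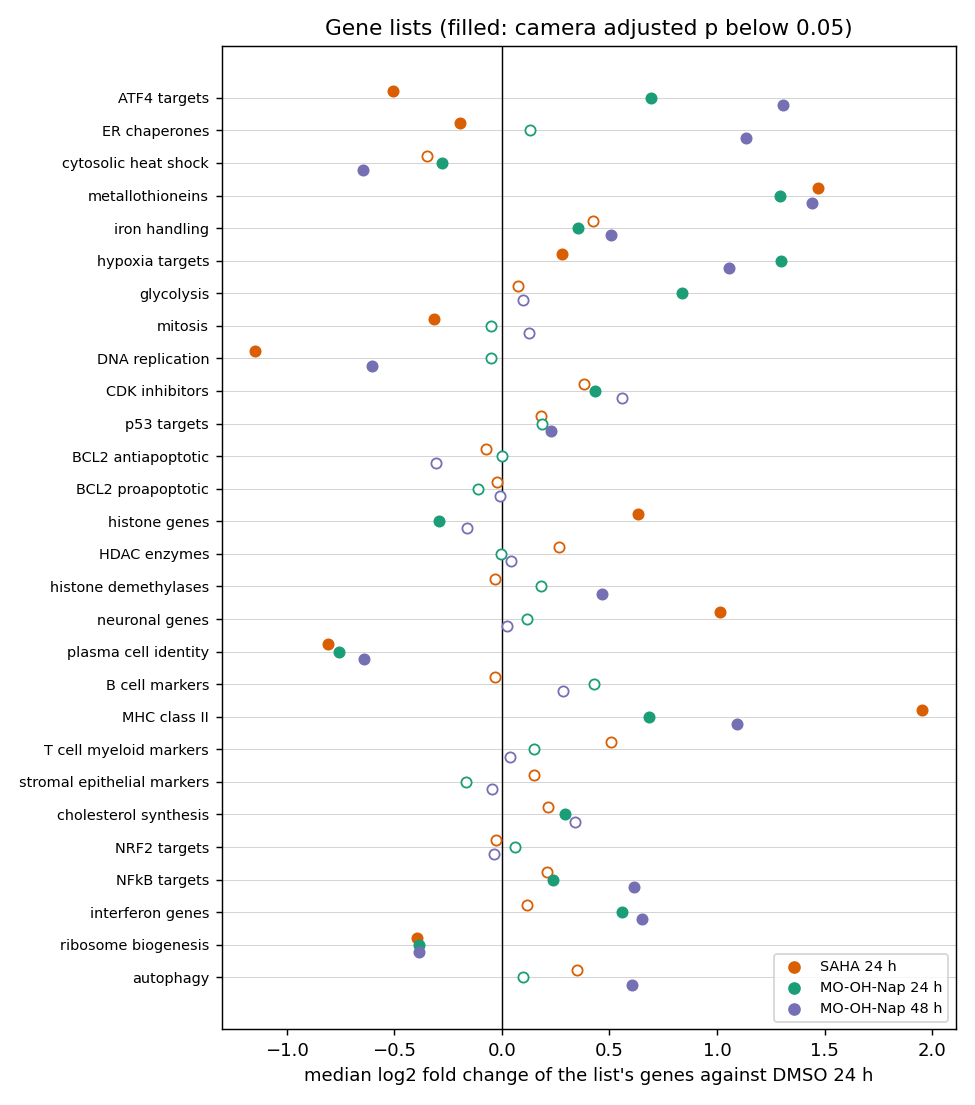
Median log2 fold change against DMSO at 24 h (x axis, fitted values) of the measured genes in each of the 28 gene lists (y axis), for SAHA at 24 h and MO-OH-Nap at 24 h and 48 h. Filled points passed camera at its preset correlation: 11 lists for SAHA, 14 for MO-OH-Nap at 24 h and 15 at 48 h, of which 3, 5 and 5 also passed with an estimated correlation.

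The next question was what MO-OH-Nap changed after 24 h. ATF4 and CHOP targets rose in 13 of 22 cases and fell in 0, with ATF3 at 2.29 ± 0.10 and DDIT4 at 1.90 ± 0.09. DDIT3, which encodes CHOP, rose from a mean log2 intensity of 7.62 to 9.61 (adjusted p = 4.8e-07). Hypoxia-inducible factor targets rose in 14 of 18 cases, among them the glycolytic regulators PFKFB4 (2.36 ± 0.12) and PFKFB3 (2.24 ± 0.16) and the prolyl hydroxylase gene P4HA2 (1.72 ± 0.09), and ADM fell. Glycolytic enzyme genes rose in 11 of 16 cases, with HK2 at 2.26 ± 0.13, ENO2 at 1.35 ± 0.08 and ALDOA at 1.18 ± 0.10. Plasma cell identity genes fell in 10 of 17 cases and rose in 0, with the coactivator gene POU2AF1 at −1.99 ± 0.09, CCND1 at −1.78 ± 0.08, XBP1 at −1.05 ± 0.08 and the transcription factor IRF4 at −0.97 ± 0.08. TFRC, the transferrin receptor gene, rose by 0.94 ± 0.07 (adjusted p = 4.5e-06), and no other of the 8 measured iron handling genes was called.

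MHC class II genes rose in 5 of 6 cases with MO-OH-Nap at 24 h, with HLA-DRB1 at 1.51 ± 0.17 and HLA-DMB at 1.15 ± 0.10. Metallothioneins rose in 6 of 7 cases, with MT2A at 1.64 ± 0.16 and MT1X at 1.51 ± 0.09, while the zinc exporter gene SLC30A1 in the same list fell. Interferon genes rose in 6 of 16 cases, among them ISG15 (2.30 ± 0.31) and IFI27 (1.63 ± 0.26). Ribosome biogenesis genes fell in 6 of 15 cases, such as NOP16 (−0.95 ± 0.11) and BOP1 (−0.90 ± 0.09). Histone genes fell in 4 of 12 cases, with H1-2 at −0.76 ± 0.09. Of 10 cytosolic heat shock genes 1 was called, HSPA1B (−0.99 ± 0.10), and 4 were lower with median scaling. Of 5 CDK inhibitor genes, CDKN1A (1.59 ± 0.07) and CDKN2D (0.93 ± 0.09) rose and CDKN2B (−0.91 ± 0.13) fell, although the other detected probe of CDKN1A gave 0.01. The NF-kB targets called were IER3 and TRAF1, of 11, and the cholesterol synthesis genes called were SCD and SREBF1, of 16. All 4 were higher, and all 4 lost their calls without background correction. The other detected probe of TRAF1 gave −0.05. IER3 also lost it without DMSO replicate 2 (0.56) and without MO-OH-Nap replicate 1 (0.54), and SCD without DMSO replicate 1 (0.58) and without MO-OH-Nap replicate 1 (0.58). Of 22 DNA replication genes 1 was called, MCM5 (−0.77 ± 0.08), and the list did not pass (adjusted p = 0.48).

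The largest rises with MO-OH-Nap at 24 h were those of COXFA4L3 (5.08 ± 0.09), S100A10 (2.68 ± 0.08), NIBAN2 (2.59 ± 0.11), the protease gene PRSS8 (2.42 ± 0.14) and the cytokine subunit gene IL23A (2.37 ± 0.12), and UPK1A, not detected with DMSO, was at least 4.39-fold higher. Other detected probes of COXFA4L3 gave 1.16 to 3.29 and that of NIBAN2 gave 0.51. Among the largest falls were 3 globin genes, HBB (−2.17 ± 0.10), HBG1 (−2.03 ± 0.12) and HBD (−1.97 ± 0.11), with TIMD4 (−2.23 ± 0.10) and POU2AF1. ADTRP, not detected with MO-OH-Nap, was at least 3.58-fold lower. MYC was at −0.76 ± 0.14 (adjusted p = 0.0026), a call lost without background correction and with an offset of 50. Values that did not pass were 0.15 ± 0.07 for ATF4, 0.11 ± 0.07 for HSPA5, 0.56 ± 0.12 for HMOX1 and −0.13 ± 0.23 for MKI67. HMOX1 passed without DMSO replicate 2 (0.62) and without MO-OH-Nap replicate 3 (0.60).

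At 24 h MO-OH-Nap changed 1667 genes and probes, 912 higher and 755 lower, of which 404 changed at least 2-fold. By camera 14 lists passed, and 5 of them held with an estimated correlation: ATF4 targets (adjusted p = 4.4e-13, and adjusted p = 0.0029 with an estimated correlation), glycolysis (1.5e-10, and adjusted p = 0.0057 with an estimated correlation), plasma cell identity (9.5e-09, and adjusted p = 0.012 with an estimated correlation), ribosome biogenesis (1.9e-06, and adjusted p = 0.0057 with an estimated correlation) and MHC class II (4.2e-05, and adjusted p = 0.015 with an estimated correlation). Hypoxia targets (1.6e-10), metallothioneins (0.0014), heat shock (0.0073, lower), iron handling (0.014) and cholesterol synthesis (0.014) each came to adjusted p = 0.062 with an estimated correlation. Histone genes (0.0073, lower) came to adjusted p = 0.068 with an estimated correlation, NF-kB targets (0.0096) to adjusted p = 0.083, CDK inhibitors (0.033) to adjusted p = 0.087 and interferon genes (0.0013) to adjusted p = 0.22, all with an estimated correlation. The remaining 14 lists had adjusted p from 0.19 to 0.81. Counts adjusted over the list alone were the same in all 28 lists. Median, mean and test differed in sign for HDAC enzymes, proapoptotic BCL2 genes and stromal or epithelial markers, none past the test. Without background correction 601 genes and probes were called, and with an offset of 50 the count was 994. With median scaling 804 were higher and 983 lower, so that most calls were lower.

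**Figure D3:**
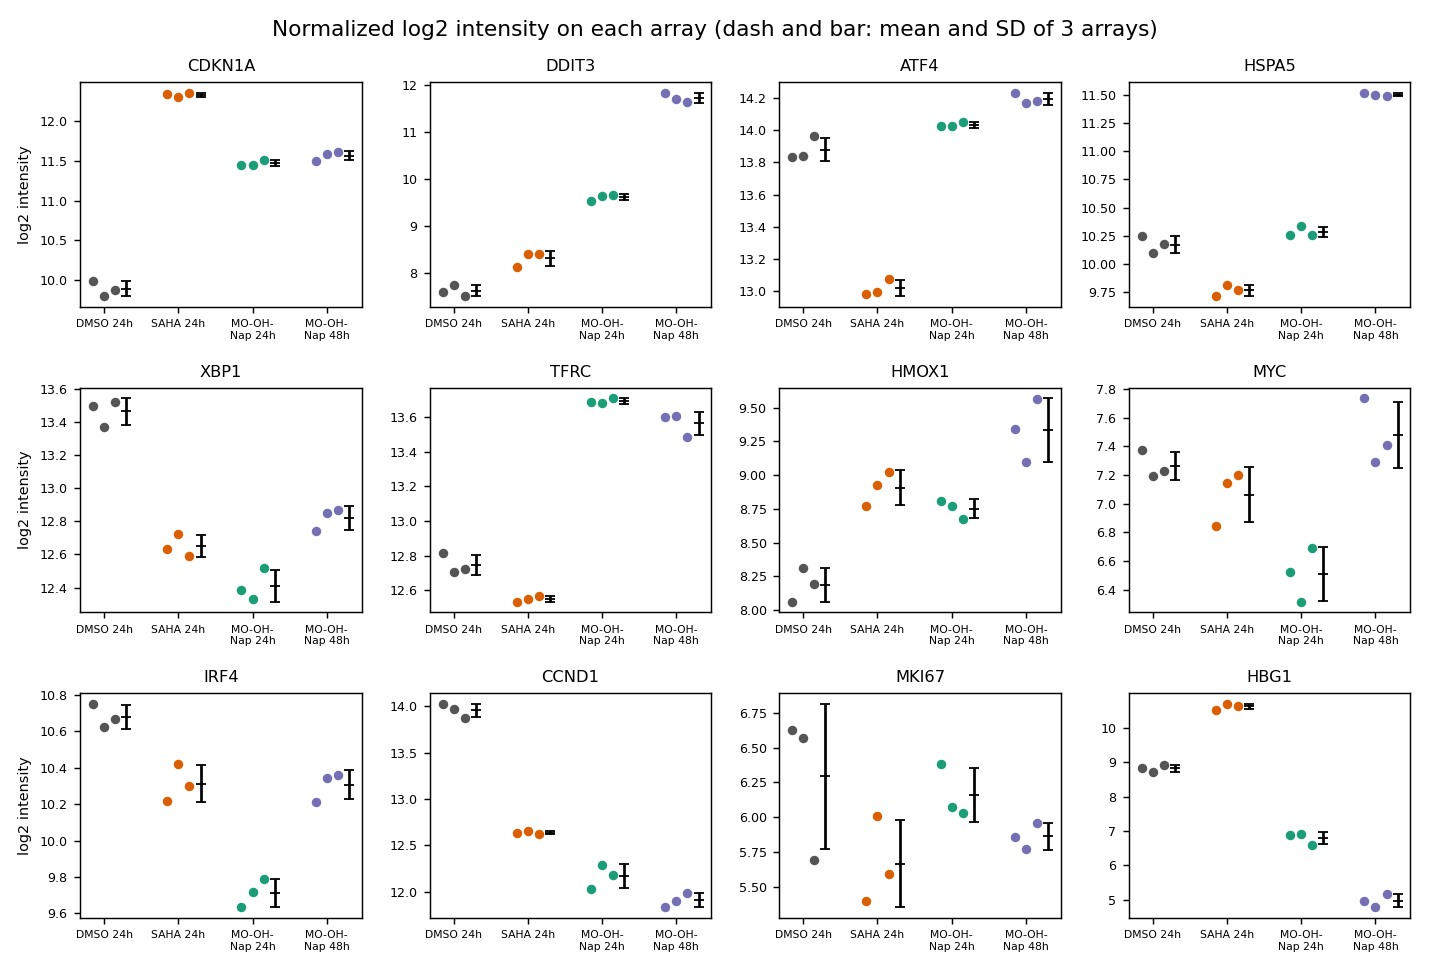
Normalized log2 intensity (y axis) of 12 genes on each of the 12 arrays, by group (x axis), with each y axis on its own range. Points are arrays, and the dash and bar beside them are the mean and SD of the 3 arrays. DDIT3 was highest with MO-OH-Nap at 48 h (4.12 above DMSO), and HBG1 was highest with SAHA (1.80 above DMSO).

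The comparison of MO-OH-Nap at 48 h with DMSO had no control of its own time, so the compound and the time in culture cannot be told apart in it. ATF4 and CHOP targets rose in 19 of 22 cases, with DDIT3 at 4.12 ± 0.10, ATF3 at 3.75 ± 0.10 and the pseudokinase gene TRIB3 at 2.81 ± 0.07. ER chaperone and ER-associated degradation genes rose in 15 of 18 cases, with DNAJB9 at 2.93 ± 0.09, HYOU1 at 1.90 ± 0.11, MANF at 1.77 ± 0.08 and HSPA5, which encodes BiP, at 1.33 ± 0.07, while XBP1 (−0.64 ± 0.08) and SEL1L fell. Hypoxia-inducible factor targets rose in 14 of 18 cases, such as ANKRD37 (1.85 ± 0.15), the histone demethylase gene KDM3A (1.73 ± 0.12) and PFKFB4 (1.67 ± 0.12). Glycolytic genes rose in 3 of 16 cases, with HK2 at 1.77 ± 0.13, and the list did not pass (adjusted p = 0.45). DNA replication genes fell in 12 of 22 cases, with MCM5 at −1.46 ± 0.08, the cyclin gene CCNE1 at −1.42 ± 0.09 and RRM2 at −1.22 ± 0.09.

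At 48 h cytosolic heat shock genes fell in 5 of 10 cases, with HSPA1B at −1.90 ± 0.10 and HSPA8 at −1.27 ± 0.08. Plasma cell identity genes fell in 9 of 17 cases, with POU2AF1 at −2.40 ± 0.09 and CCND1 at −2.04 ± 0.08, and rose in 2, CD38 and MZB1 (1.55 ± 0.15). Ribosome biogenesis genes fell in 5 of 15 cases, with BOP1 at −1.31 ± 0.09 and NOP56 at −1.29 ± 0.07. MHC class II genes rose in 5 of 6 cases, with HLA-DRB1 at 1.40 ± 0.17 and CD74 at 1.16 ± 0.12, and metallothioneins in 5 of 7, with MT1X at 3.14 ± 0.09. Autophagy genes rose in 7 of 13 cases, with ULK1 at 1.47 ± 0.11 and MAP1LC3B at 1.44 ± 0.08, and ATG7 fell. Interferon genes rose in 9 of 16 cases, with ISG15 at 1.98 ± 0.31 and IRF7 at 1.41 ± 0.13, and OAS1 fell. Of the NF-kB targets 6 of 11 rose, with RELB at 1.33 ± 0.10, and of the histone demethylases 4 of 12 rose, with KDM6A at 0.96 ± 0.12. Iron handling genes rose in 4 of 8 cases, with HMOX1 at 1.15 ± 0.12, TFRC at 0.82 ± 0.07 and the metal transporter gene SLC11A2 going from a mean log2 intensity of 7.58 to 8.58. Of 14 p53 targets 3 rose, the receptor gene TNFRSF10B (2.19 ± 0.09), GADD45A (1.59 ± 0.09) and GDF15, and TP53INP1 fell. CDKN1A stood at 1.68 ± 0.07, with its other detected probe at 0.49, and the proapoptotic gene HRK at 2.89 ± 0.15.

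The largest rises at 48 h were those of COXFA4L3 (5.45 ± 0.09), the ribosomal 5S RNA gene RNA5S9 (4.60 ± 0.11), DDIT3, and SNORD3C (4.04 ± 0.10), a U3 small nucleolar RNA. Of the same group, GDF15 was at least 17.2-fold higher and ADGRG1 at least 10.8-fold higher, neither detected with DMSO. Other detected probes of COXFA4L3 gave 0.68 to 3.08. Globin genes made up 4 of the 6 largest falls: HBG1 (−3.85 ± 0.12), HBG2 (−3.49 ± 0.21), HBD (−3.19 ± 0.11) and HBB (−2.98 ± 0.10), with HBG1 and HBB detected on 1 of 3 arrays at 48 h and HBG2 on 2 of 3. RAB36 changed by −2.77 ± 0.14, and FBP1, not detected at 48 h, was at least 5.50-fold lower. Values that did not pass were 0.31 ± 0.07 for ATF4, 0.21 ± 0.14 for MYC, −0.37 ± 0.08 for IRF4 and −0.43 ± 0.23 for MKI67. ATF4 passed when probes were averaged, and MKI67 without DMSO replicate 3 (−0.73). RNA5S9 was higher by 2.15 with SAHA, 1.43 with MO-OH-Nap at 24 h and 4.60 at 48 h, and the 7SK RNA gene RN7SK by 1.36, 0.92 and 3.02, while the 7SL RNA gene RN7SL1 was called in none of these (0.25, −0.02 and 0.41). RN7SL1 had adjusted p = 0.030 with SAHA and adjusted p = 0.0015 at 48 h, both at less than 1.5-fold. RN7SK and RN7SL1 were chosen after their values were seen.

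Against DMSO, MO-OH-Nap at 48 h changed 4046 genes and probes, 2108 higher and 1938 lower, of which 1389 changed at least 2-fold. By camera 15 lists passed, and 5 held with an estimated correlation: ATF4 targets (adjusted p = 1e-12, and adjusted p = 0.0032 with an estimated correlation), ER chaperones (4.8e-06, and adjusted p = 0.0086 with an estimated correlation), MHC class II (0.00074, and adjusted p = 0.038 with an estimated correlation), ribosome biogenesis (0.00074, and adjusted p = 0.035 with an estimated correlation) and heat shock (0.00085, and adjusted p = 0.035 with an estimated correlation). Hypoxia targets (4.8e-06) came to adjusted p = 0.14 with an estimated correlation, DNA replication (5.7e-06) to adjusted p = 0.053, plasma cell identity (0.00069) to adjusted p = 0.077 and metallothioneins (0.0018) to adjusted p = 0.082, each with an estimated correlation. For autophagy (0.0034) it was adjusted p = 0.12 with an estimated correlation, and for interferon genes (0.012) adjusted p = 0.36. Histone demethylases (0.0071), NF-kB targets (0.012), iron handling (0.044) and p53 targets (0.045) each came to adjusted p = 0.11 with an estimated correlation. The other 13 lists had adjusted p from 0.17 to 0.95, and counts adjusted over the list alone were the same in all 28 lists. Median, mean and test differed in sign for proapoptotic BCL2 genes, NRF2 targets, T cell or myeloid markers and stromal or epithelial markers, none past the test. Without background correction 1994 genes and probes were called. With median scaling the share of calls that were higher moved from 52.1% to 62.0%, and the iron handling list was lost (adjusted p = 0.081).

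Some lists passed in none of the 5 comparisons. Against DMSO the HDAC enzymes came to camera adjusted p of 0.38 with SAHA, 0.45 with MO-OH-Nap at 24 h and 0.63 at 48 h, with HDAC9 (1.36 ± 0.12, other detected probes 0.21 to 1.09) among 3 members that rose with SAHA. For NRF2 targets the values were 0.80, 0.72 and 0.92, for antiapoptotic BCL2 genes 0.55, 0.48 and 0.63, and for proapoptotic ones 0.73, 0.72 and 0.84. BCL2L1, which encodes BCL-XL, fell in all 3 comparisons, by −0.77 ± 0.08, −0.73 ± 0.08 and −1.04 ± 0.08. B cell markers came to 0.87, 0.45 and 0.75, with CD79B at −0.91 ± 0.09, −0.92 ± 0.09 and −1.62 ± 0.09. Of the markers of other cell types, 0 of 3 measured T cell or myeloid genes were called in limma (0.41, 0.64 and 0.95 for the list), though 2 with SAHA passed the adjusted p at less than 1.5-fold and 0 with MO-OH-Nap had an unadjusted p below 0.05, and 1 of 3 stromal or epithelial genes, KRT18, was higher in each (0.58, 0.81 and 0.86 for the list). KRT18 was detected on 1 of 3 arrays with DMSO and lost all 3 calls without background correction. At 24 h with MO-OH-Nap it also lost the call without DMSO replicate 2 (0.58) and without MO-OH-Nap replicate 2 (0.58).

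A direct comparison of the compounds at 24 h asked where their profiles differ, with doses not given in the sources used here. DNA replication genes were higher with MO-OH-Nap than with SAHA in 18 of 22 cases, with RRM2 at 2.24 ± 0.09, CDC45 at 2.09 ± 0.08 and CDT1 at 1.91 ± 0.09. ATF4 and CHOP targets were higher in 19 of 22 cases, with STC2 at 3.07 ± 0.12, the serine synthesis gene PSAT1 at 2.15 ± 0.08 and the cystine transporter gene SLC7A11 at 2.01 ± 0.14. Glycolytic genes were higher in 12 of 16 cases, with HK2 at 2.43 ± 0.13 and ENO2 at 1.66 ± 0.08, and hypoxia targets in 13 of 18, with SLC2A1 at 2.85 ± 0.15. Of the latter ADM and MXI1 were lower. Histone genes were lower with MO-OH-Nap in 8 of 12 cases, with H2AC6 at −1.77 ± 0.10 and H1-2 at −1.77 ± 0.09, and MHC class II genes in 4 of 6, with HLA-DMB at −2.27 ± 0.10. ER chaperones were higher in 5 of 18 cases, with DNAJB9 at 1.88 ± 0.09 and MANF at 1.19 ± 0.08.

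The largest differences at 24 h, MO-OH-Nap minus SAHA, were those of the cytokine gene IL32 (3.51 ± 0.11), SLC6A9 (3.40 ± 0.14), STC2, PRSS8 (2.90 ± 0.14) and SLC2A1 on the higher side. The other detected probes of SLC6A9 gave 0.13 to 0.25 and that of IL32 gave 1.82. With SAHA, IL32 was detected on 2 of 3 arrays and PRSS8 on 1 of 3. On the lower side were IDO1 (−4.31 ± 0.11), which encodes an enzyme of tryptophan breakdown, the fetal globin genes HBG1 (−3.83 ± 0.12) and HBG2 (−3.68 ± 0.21), AKR1C3 (−3.44 ± 0.14) and PCDH20 (−3.27 ± 0.17). CDKN1A was lower by −0.86 ± 0.07, and TFRC (1.14 ± 0.07), DDIT3 (1.30 ± 0.10) and ATF4 (1.01 ± 0.07) were higher, although the other detected probes of ATF4 ranged from −0.32 to 1.48. IRF4 (−0.60 ± 0.08) was lower, a call that ended without background correction, with an offset of 50, with median scaling, without SAHA replicate 2 (−0.54) and without MO-OH-Nap replicate 1 (−0.56). Several differences did not pass. XBP1 differed by −0.24 (95% interval −0.42 to −0.06), HMOX1 by −0.16 (−0.43 to 0.11), CCND1 by −0.47 (−0.65 to −0.29), HSPA5 by 0.52 (0.37 to 0.67), MYC by −0.55 (−0.87 to −0.24) and MKI67 by 0.50 (−0.02 to 1.01). HSPA5 passed with median scaling, and MYC without SAHA replicate 1 (−0.67) and without MO-OH-Nap replicate 3 (−0.65).

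Between the compounds 3651 genes and probes differed at 24 h, 1738 higher and 1913 lower with MO-OH-Nap, of which 1243 differed at least 2-fold. By camera 7 lists passed: ATF4 targets (adjusted p = 5.1e-13, and adjusted p = 0.0029 with an estimated correlation), DNA replication (1.9e-12, and adjusted p = 0.017 with an estimated correlation), glycolysis (9.6e-06), histone genes (0.00031), MHC class II (0.00048) and ER chaperones (0.0043), the last 4 each with adjusted p = 0.036 with an estimated correlation. Hypoxia targets (0.00048) came to adjusted p = 0.48 with an estimated correlation. The remaining 21 lists had adjusted p from 0.082 (neuronal genes) to 0.999. Adjusted over the list alone, 7 interferon genes in place of 6 were higher and 3 proapoptotic BCL2 genes in place of 2 were lower. Median, mean and test differed in sign for HDAC enzymes, proapoptotic BCL2 genes, histone demethylases, NF-kB targets and ribosome biogenesis genes, none past the test. Without background correction 1672 were called, and median scaling moved the share that was higher from 47.6% to 58.2%.

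Overlap of the compounds at 24 h was measured on their calls against the same 3 DMSO arrays. Both raised 414 genes and probes, where independence gives 100.5, and both lowered 289, where it gives 75.8. Among the shared genes were COXFA4L3 and HLA-DMB, higher with both, and CCND1, XBP1 and ADTRP, lower with both. CDKN1A was shared on its brightest probe, while its other detected probe gave 1.24 with SAHA and 0.01 with MO-OH-Nap. At an unadjusted p below 0.05 and 1.5-fold 730 were shared, against a mean of 16.06 (6 to 25) in 100 simulations of unchanged groups that share 3 controls. The controls are too few to be split, so part of the excess may come from sharing them. Across genes, which are not independent replicates, the fold changes correlated at 0.389 (Pearson) and 0.367 (Spearman). Shared controls without any effect gave 0.499 and 0.461 on average. Those simulated values follow from sharing controls between groups of equal size, so they cannot tell how alike the 2 profiles are. The covariance was 0.0861, against 0.0143 in the simulations. Without background correction 235 calls were shared in place of 703, and with an offset of 50 the number was 405.

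A set of 104 genes and probes moved in opposite directions, 44 higher with SAHA and lower with MO-OH-Nap and 60 the other way. All 104 also differed directly between the compounds, which opposite calls in the same fit all but ensure. IDO1 changed by 3.50 ± 0.11 with SAHA and −0.81 ± 0.11 with MO-OH-Nap, HBG1 by 1.80 ± 0.12 and −2.03 ± 0.12, and HBG2 by 1.82 ± 0.21 and −1.85 ± 0.21. In the other direction IL32 changed by −1.15 ± 0.11 and 2.36 ± 0.11 and SLC6A9 by −2.52 ± 0.14 and 0.88 ± 0.14, on its brightest probe alone, since its other detected probes gave −0.16 to −0.04 with SAHA. Without background correction 29 genes and probes moved in opposite directions, and with an offset of 50 the number was 50.

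**Figure D4:**
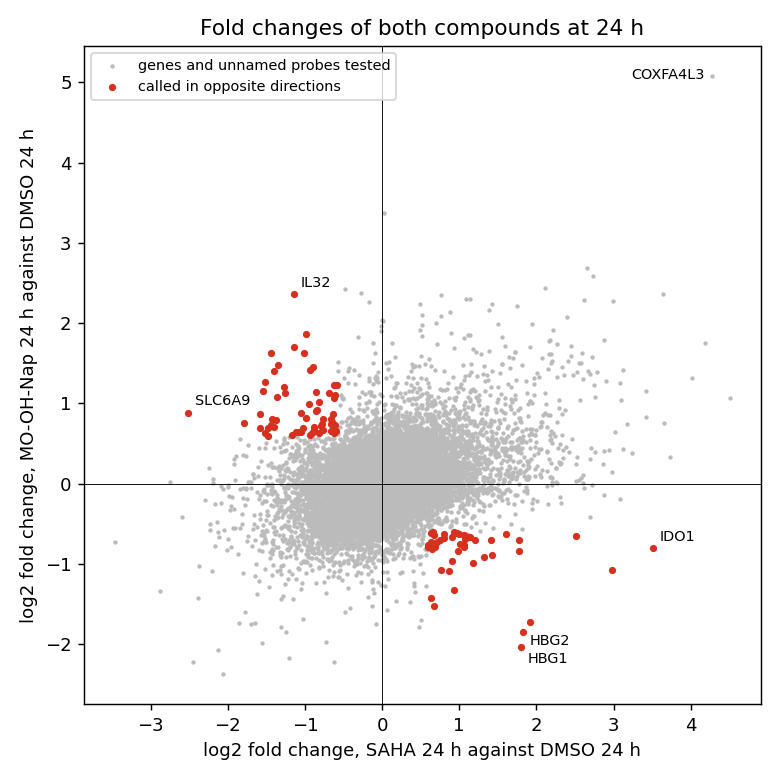
Log2 fold change against DMSO at 24 h of each gene or unnamed probe with SAHA (x axis) and with MO-OH-Nap (y axis). Red points are the 104 called in opposite directions, and COXFA4L3 stands highest with MO-OH-Nap (5.08) and at 4.28 with SAHA.

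The last comparison set MO-OH-Nap at 48 h against 24 h, a difference of time that also holds the time in culture. ER chaperones were higher at 48 h in 14 of 18 cases, with HYOU1 at 1.53 ± 0.11, HSP90B1 at 1.29 ± 0.08, PDIA4 at 1.24 ± 0.12 and HSPA5 at 1.22 ± 0.07. ATF4 and CHOP targets were higher in 12 of 22 cases, with DDIT3 at 2.12 ± 0.10, PPP1R15A at 1.92 ± 0.08 and ATF3 at 1.46 ± 0.10. Glycolytic genes were lower in 8 of 16 cases, with PGAM1 at −1.11 ± 0.07, TPI1 at −1.10 ± 0.09 and ALDOA at −1.02 ± 0.10, and DNA replication genes in 8 of 22, with RRM2 at −1.56 ± 0.09 and CCNE1 at −1.38 ± 0.09. Heat shock genes were lower in 4 of 10 cases, with HSPA1B at −0.91 ± 0.10. Autophagy genes were higher in 4 of 13 cases, with WIPI1 at 1.29 ± 0.09 and MAP1LC3B at 1.17 ± 0.08, and 8 were higher with median scaling. Histone demethylases were higher in 3 of 12 cases, KDM7A, KDM5B and KDM6A, with all 3 calls lost without background correction. KDM5B also lost it without 24 h replicate 3 (0.49) and 48 h replicate 3 (0.43), and KDM6A without 24 h replicate 3 (0.57) and 48 h replicate 1 (0.56).

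The largest rises from 24 to 48 h were those of ADGRG1 (3.47 ± 0.18, detected on 2 of 3 arrays at 24 h), RNA5S9 (3.17 ± 0.11), SNORD3C (2.68 ± 0.10) and GDF15 (2.64 ± 0.12), a stress-induced cytokine, and the intermediate filament gene PRPH, not detected at 24 h, was at least 4.95-fold higher. The largest falls were those of ZSCAN10 (−1.96 ± 0.24, detected on 1 of 3 arrays at 48 h), TMSB15A (−1.82 ± 0.19), HBG1 (−1.82 ± 0.12, also detected on 1 of 3 arrays at 48 h), SLC25A47 (−1.80 ± 0.10) and NECAB1 (−1.65 ± 0.35). MYC was higher by 0.97 ± 0.14, a call lost without background correction, and IRF4 by 0.59 ± 0.08, a call lost without background correction, with an offset of 50, with array weights, without 24 h replicate 1 (0.55), without 48 h replicate 2 (0.58) and without 48 h replicate 3 (0.57). Values that did not pass were 0.09 ± 0.07 for CDKN1A, 0.16 ± 0.07 for ATF4, 0.41 ± 0.08 for XBP1, −0.13 ± 0.07 for TFRC, 0.58 ± 0.12 for HMOX1, −0.26 ± 0.08 for CCND1 and −0.30 ± 0.23 for MKI67. HMOX1 passed with median scaling, with array weights and without any of 5 single arrays, where it ranged from 0.59 to 0.71.

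From 24 to 48 h 2108 genes and probes changed, 1087 higher and 1021 lower, of which 419 changed at least 2-fold. By camera 7 lists passed: ER chaperones (adjusted p = 1.1e-09, and adjusted p = 0.0027 with an estimated correlation), glycolysis (9.4e-09, and adjusted p = 0.01 with an estimated correlation), ATF4 targets (2.1e-08, and adjusted p = 0.0078 with an estimated correlation), DNA replication (2.1e-08, and adjusted p = 0.03 with an estimated correlation), autophagy (0.0018), heat shock (0.0089) and histone demethylases (0.036). The last 3 came to adjusted p = 0.15, adjusted p = 0.066 and adjusted p = 0.21 with an estimated correlation. The other 21 lists had adjusted p from 0.064 (p53 targets) to 0.894. Counts adjusted over the list alone were the same in all 28 lists. Median, mean and test differed in sign for metallothioneins, plasma cell identity, CDK inhibitors and proapoptotic BCL2 genes, none past the test. Without background correction 845 were called, and with an offset of 50 the count was 1369. Median scaling moved the share that was higher from 51.6% to 77.2% and the median of all genes to 0.10.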

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

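The tests in this part were chosen after the results were seen, apart from the counts over other splits of the arrays. The results listed first differ between the 2 time points of MO-OH-Nap by a direct test of the 48 h arrays against the 24 h arrays, with 3 arrays each and no DMSO control at 48 h. Between the times 2108 genes and probes changed, 1087 higher and 1021 lower at 48 h. With median scaling 1869 were higher and 551 lower. Lists higher at 48 h were ER chaperones (adjusted p = 1.1e-09), ATF4 and CHOP targets (2.1e-08), autophagy (0.0018) and histone demethylases (0.036), the last 2 with adjusted p = 0.15 and adjusted p = 0.21 with an estimated correlation. Lists lower at 48 h were glycolysis (9.4e-09), DNA replication (2.1e-08) and heat shock (0.0089, and adjusted p = 0.066 with an estimated correlation). The log2 differences were 3.47 for ADGRG1, 3.17 for RNA5S9, 2.68 for SNORD3C, 2.64 for GDF15, 2.12 for DDIT3, 1.22 for HSPA5, 0.97 for MYC and 0.59 for IRF4, and PRPH was at least 4.95-fold higher. On the lower side they were −1.96 for ZSCAN10, −1.82 for TMSB15A, −1.82 for HBG1, −1.80 for SLC25A47 and −1.65 for NECAB1.

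For each comparison the 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05, and in each case 1 split, the real one, gave the highest count. The real split called 3687 features for SAHA against DMSO (highest other split 0), 1667 for MO-OH-Nap at 24 h (0), 4046 at 48 h (0), 3651 between the compounds (1) and 2108 between the times (0). For lists the real counts and the highest others were 11 and 6, 14 and 10, 15 and 12, 7 and 5, and 7 and 6. Each side of every other split holds 2 arrays of 1 group and 1 of the other. Part of the real difference thus stays between the sides, and the rest widens the spread within them. Counts from the other splits are therefore no baseline for what unchanged arrays would give.

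The 5S RNA gene RNA5S9, the U3 genes SNORD3A, SNORD3C and SNORD3D and the 7SK gene RN7SK stood 3.02 to 4.60 higher on the log2 scale at 48 h than with DMSO. A higher yield of all small RNAs as the whole cause is argued against, since 62 other small noncoding RNAs detected on all arrays had a median of −0.13 against DMSO, with an upper quartile of 0.41. A higher yield of some of them stays open, since RNU4-2 (2.39), RNU4-1 (2.33), SNORD13 (1.95), RNU6-1 (1.58) and RNU1-1 (1.26) were higher too. By camera the list of 130 small noncoding RNA genes was higher at 48 h than at 24 h (adjusted p = 0.0015, and adjusted p = 0.064 with an estimated correlation). That list holds the 5 RNAs themselves and was chosen after the values were seen, so its result cannot decide this. The smallest gap between a 48 h array and a DMSO array over these 5 RNAs was 2.92. Every 48 h array therefore held the rise. This describes the 5 RNAs and is no test. RNA5S9 and SNORD3C were named by a rule that asks for arrays without overlap, and the others were chosen after their values were seen. Time in culture alone is argued against for the rise seen at 24 h, where all 5 were already higher than DMSO of that time. For the further rise from 24 to 48 h (median 2.18) the compound and time in culture cannot be told apart without a control at 48 h, and a change in how these RNAs were recovered or labelled was not tested.

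Under SAHA the globin genes moved apart: HBG1, HBG2 and HBA2 rose by 1.80, 1.82 and 1.36 and HBE1 and HBA1, not detected with DMSO, were called higher, while HBB and HBD fell. If all globin probes read 1 transcript they would move together, but HBD was at −0.72 and HBB at −1.20. A larger share of erythroid cells that make adult beta globin would raise HBB, which fell. Both falls belong to the pattern as it was chosen after the values were seen, so neither is a separate test. All arrays are of U266, a myeloma cell line, and HBG1 and HBG2 were detected on all 3 DMSO arrays. Nothing in the labels names erythroid cells, and a share of such cells with little HBB was not tested. All 4 normalizations kept HBG1 and HBG2 higher and HBB lower, which argues against the normalization. The probes of HBG1 and HBG2 cannot be told apart in what they read, since these genes are nearly identical and differed by 0.0286, and an effect of SAHA on the globin genes of the cells themselves stays open.

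ATF4 and CHOP targets and ER chaperones were higher at 48 h, where time in culture and the compound coincide. Of the 19 ATF4 and CHOP targets higher at 48 h, 13 were already called higher at 24 h against DMSO of the same time, which argues against time in culture as the whole cause for that list. Of the 15 ER chaperones higher at 48 h, 3 were already higher at 24 h, so for the chaperones time in culture and the compound cannot be told apart with no DMSO control at 48 h.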

How the results depend on the processing

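All alternatives were planned except the list directions under other normalizations, which were added after seeing the data. In the order SAHA, MO-OH-Nap at 24 h, MO-OH-Nap at 48 h (each against DMSO), MO-OH-Nap against SAHA, 48 h against 24 h, calls shared by the compounds and opposite calls, the counts were 3687, 1667, 4046, 3651, 2108, 703 and 104. With the deposited log2 values, and equally with quantile normalization without background correction, they were 1739, 601, 1994, 1672, 845, 235 and 29. In the 5 comparisons 1739, 601, 1993, 1671 and 845 of these were also main calls, so almost no other call appeared. Background left in the signals makes log2 ratios smaller, and how much of the drop this explains was not tested. An offset of 50 gave 994 for MO-OH-Nap at 24 h, 1369 for 48 h against 24 h, 405 shared and 50 opposite. Of the first 2 counts 993 and 1366 were also main calls. A larger offset also makes log2 ratios smaller, and its share in the drop was not tested. Without a fold requirement the counts were 7278, 4401, 7454, 6957, 5303, 2271 and 652, with 2-fold 1319, 404, 1389, 1243, 419, 170 and 15, and with treat 1454, 338, 1540, 1336, 385, 150 and 14, by the construction of these thresholds. All other settings left each of these counts within 1.5 times. Without each array in turn they ranged over 3546 to 3745, 1641 to 1739, 3943 to 4054, 3514 to 3672, 2062 to 2162, 689 to 740 and 97 to 112, the correlation across genes over 0.376 to 0.410, and the named calls over 374 to 383 of a main 384. Replicate number as a block gave 3669, 1656, 4023, 3637 and 2103. Camera with an estimated correlation passed 3, 5 and 5 lists against DMSO in place of 11, 14 and 15, and 4 in place of 7 between the times, and ended 31 of 54 list calls. With fry 26, 22, 24, 16 and 15 lists passed in place of 11, 14, 15, 7 and 7, since fry does not compare a list with other genes. No named gene or list that was called reversed. Of the 384 named calls 82 ended without background correction, 32 with an offset of 50, 25 with median scaling and 10 with averaged probes, and at most 11 in any other of these settings. No called list turned direction under any of the normalizations. A chip effect was not run, since no chip is named. Signal over background limits what dim probes can show: 21489 of 47318 probes passed the detection filter.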

Other observations

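The lists in this part were chosen after the values were seen, as were their tests. Their p-values are adjusted over these 7 lists alone in each comparison. Since the same arrays gave the choice and the test, the p-values add no independent support. Genes of the mitochondrial ribosome fell with both compounds: 18 of 76 with SAHA (adjusted p = 5.6e-08, and adjusted p = 0.023 with an estimated correlation), 9 with MO-OH-Nap at 24 h (2.3e-12, and adjusted p = 0.011 with an estimated correlation) and 28 at 48 h, where MRPL10 rose (2.2e-10, and adjusted p = 0.014 with an estimated correlation). MRPL12 changed by −0.91 ± 0.12, −0.81 ± 0.12 and −1.36 ± 0.12 in these comparisons. Complex I subunit genes fell in 15 of 34 cases at 48 h (1.5e-08, and adjusted p = 0.014 with an estimated correlation), with NDUFA13 at −1.01 ± 0.11 and NDUFB8 at −0.98 ± 0.10. With SAHA 7 fell (0.0045, and adjusted p = 0.14 with an estimated correlation). At 24 h with MO-OH-Nap the list passed (0.00047, and adjusted p = 0.071 with an estimated correlation) with fold changes of −0.56 to 0.29 and no single gene called. Proteasome genes fell in 8 of 34 cases with SAHA (3.4e-05, and adjusted p = 0.023 with an estimated correlation), 1 with MO-OH-Nap at 24 h (3.9e-07, and adjusted p = 0.011 with an estimated correlation) and 10 at 48 h (4.4e-08, and adjusted p = 0.014 with an estimated correlation). PSMB6 was lower in all 3 (−0.74 ± 0.07, −0.70 ± 0.07 and −0.92 ± 0.07).

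Amino acid transporter genes differed between the compounds. SLC7A11 and SLC3A2 of this list also stand on the list of ATF4 and CHOP targets, as do WARS1 and SARS1 of the tRNA synthetases. The results of these lists are therefore not separate from it. With SAHA the fall of SLC6A9 was seen on its brightest probe alone. Of 12 amino acid transporter genes 8 fell and 2 rose with SAHA (adjusted p = 0.0045, and adjusted p = 0.023 with an estimated correlation), with SLC7A5 at −1.91 ± 0.08 and SLC1A5 at −1.44 ± 0.10. With MO-OH-Nap at 24 h 4 rose and 1 fell (0.0036, and adjusted p = 0.023 with an estimated correlation), and SLC1A5 stood at 0.73 ± 0.10. Directly compared, 7 were higher and 2 lower with MO-OH-Nap (0.00045, and adjusted p = 0.013 with an estimated correlation). Of 16 tRNA synthetase genes 7 fell with SAHA (0.00077, and adjusted p = 0.023 with an estimated correlation), among them WARS1 (−0.92 ± 0.07), and the same number were higher with MO-OH-Nap than with SAHA (0.0016, and adjusted p = 0.025 with an estimated correlation). Against DMSO 1 fell with MO-OH-Nap at 24 h and the list did not pass (adjusted p = 0.985), and at 48 h 4 rose and 1 fell (0.027, and adjusted p = 0.067 with an estimated correlation). Of the 7 globin genes 5 rose and 2 fell with SAHA, and the list did not pass (0.11). With MO-OH-Nap 4 fell at 24 h (0.00047, and adjusted p = 0.023 with an estimated correlation) and 4 at 48 h, where HBE1 rose (0.0037, and adjusted p = 0.036 with an estimated correlation). Of 130 small noncoding RNA genes 23 rose and 8 fell with SAHA (0.39), 8 rose and 16 fell with MO-OH-Nap at 24 h (0.074) and 27 rose and 15 fell at 48 h (0.44). Between treated groups the same list passed: 30 were higher and 6 lower at 48 h than at 24 h (0.0015, and adjusted p = 0.064 with an estimated correlation), and 3 were higher and 27 lower with MO-OH-Nap than with SAHA (0.0074, and adjusted p = 0.14 with an estimated correlation). RPPH1, the RNA of ribonuclease P, rose with SAHA (2.21 ± 0.07). It did not pass with MO-OH-Nap at 24 h (0.50 ± 0.07, below 1.5-fold) or at 48 h (−0.14 ± 0.07).

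A hypothesis for the rise of hypoxia-inducible factor targets and TFRC with MO-OH-Nap at 24 h is that less iron may be available in the cells, as both respond to iron. The hypoxia list came to adjusted p = 0.062 with an estimated correlation. SLC11A2, another gene whose RNA rises when iron is short, stood at 0.34 (SE 0.09, adjusted p = 0.0218), past the adjusted p but below 1.5-fold. That value neither meets nor excludes the hypothesis. SLC11A2 was called higher at 48 h (from a mean log2 intensity of 7.58 to 8.58), where the compound and time in culture coincide, and higher by 0.99 than with SAHA at 24 h (adjusted p = 9.4e-06), where it fell with SAHA (−0.65). Iron was not measured.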
